A study of Mus musculus with 9 samples.

How the data were processed

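RNA bound by FMRP, the RNA-binding protein lost in fragile X syndrome, or by the neuronal Hu proteins was mapped in mouse brain polyribosomes by HITS-CLIP. In this assay ultraviolet light fixes proteins to the RNA they touch, the protein is immunoprecipitated, and the short RNA fragments that come with it are sequenced as tags. Per the labels' protocols, polyribosomes came from cortex and cerebellum, freed of white matter, of FVB mice, and the series text describes pooled littermates. FMRP was precipitated with a mixture of monoclonal antibodies (7G1-1 together with 2F5) or with a polyclonal antibody, and Hu proteins with a human antiserum. The 5 libraries of Protocol 1 (dissociation in 1% SDS) were sequenced on the 454 platform, and the 4 libraries of Protocol 2 (2% SDS) on Illumina. Per the series text, the P11 and the P13 lysate were each divided between the polyclonal FMRP antibody and the Hu antiserum.

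The submitters' processing notes name Novoalign as the aligner and mm9 as the genome build, with no version. Each library has a list of unique tags placed on the genome and a list of unique tags placed on RefSeq transcripts, in the sense direction. In the 454 lists the deposited value beside each tag holds counts of the reads merged into each tag, going by the values. In the Illumina lists the deposited value is a score of no stated meaning, which was not used. A line was counted as 1 tag in both kinds of list. The authors' gene table gives whole-number tag counts per gene for the 7 FMRP libraries, over the whole transcript and over the coding sequence. It also holds 3 columns treated here as scores: the number of FMRP libraries with a tag, a chi-square statistic, and an FDR that exceeds 1 in many lines, all as deposited by the authors. The p-value in that table is the authors' own, and how it was reached is not given in the sources used here. An exon array intensity per gene and a log2 expression value in neurons are deposited in the table too, and per the file headers they come from other measurements; only the intensity was used here. Transcript and coding lengths, mm9 gene bounds and membership of published gene collections were taken from the same table.

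Tags on transcripts were summed to 11622 genes. Of these, 10603 were named from a table of gene identifiers, 699 from the authors' table, and 320 kept their accession or identifier. The authors' table has 30999 lines, of which 8976 genes have at least 1 tag, and 7967 of these also have a tag in the transcript lists. Each of the 7 FMRP count columns was matched to its library by antibody, age and protocol. FMRP was compared with Hu on the transcript tags, since the Hu libraries have no column in the authors' table. The antibody, age and protocol comparisons used the authors' counts. An annotation of mm9 was not used here, so the share of tags in coding sequence rests on the authors' coding counts for FMRP, and the position of the tag middle along the transcript was used for all 9 libraries. This last measure was chosen after the data were examined.

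Libraries held 4397 to 7713 transcript tags on 454 and 25873 to 49847 on Illumina. A gene with 0 tags could still hold up to 3 counts, which corresponds to 682 CPM (tag counts scaled to a common library total) in the smallest library and 60.2 CPM in the largest. Intervals for shares are Wilson intervals at 95%. Intervals and floors cover counting error only. Replicates of a group differ in age, and each is a pool of mice, so p-values measure the spread between these libraries.

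Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr, the quasi-likelihood test in the default form of that version, and Benjamini-Hochberg adjustment at 0.05. FMRP against Hu was fitted on the 4 Illumina libraries with group as the only term. Antibody was fitted on the 5 libraries of Protocol 1, age (P25 against P14 and P15) on the same libraries with antibody as a term, and protocol on the 4 libraries made with the polyclonal FMRP antibody. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 3 members were tested, with fry beside it, and again with an estimated correlation. A fold against a group with 0 tags was computed against 3 counts over the whole group and is a lower bound. With few tags, ratios of library-scaled tag totals carry an exact counting interval. Clustering was measured as the share of tags overlapped by at least 10 others after every library was thinned to the smallest one, as the mean of 20 draws. Permutation tests were exact for groups of libraries and used 100000 resamples across genes. All tests are two-sided. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

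The groups, tests, gene lists and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule takes, for each comparison, the 10 genes with the largest fold change in each direction among those past the threshold with a mean of at least 50 CPM, or the 3 smallest p in each direction where none passed. It adds up to 4 members of each list, the called members with the smallest adjusted p, a set of 10 genes named in advance (Fmr1, Map1b, Dlg4, Arc, Camk2a, App, Shank3, Grm5, Gap43 and Elavl4), and the 10 genes with the highest mean CPM in the FMRP and in the Hu libraries. The 20 lists cover glutamate receptors, postsynaptic scaffolds and signalling, the presynaptic vesicle and active zone, voltage-gated ion channels, small GTPase regulators, PI3K-mTOR signalling, cytoskeleton and motors, chromatin regulators, autism-risk genes, adhesion and guidance receptors, cytosolic ribosomal proteins, oxidative phosphorylation, RNA-binding proteins, known Hu-bound mRNAs, activity-induced genes, and markers of cerebellar neurons, astrocytes, oligodendrocytes and myelin, microglia and endothelium.

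The pairing of FMRP and Hu libraries by lysate comes from the series text. As a check, the change from P11 to P13 in FMRP and in Hu correlated across 1015 genes with r = 0.161, and genes are not independent replicates. Alternatives were DESeq2's size factors, library totals without TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, genomic tags within gene bounds, the age as a block, all 7 FMRP libraries with a platform term, and leaving out each library. With the platform term the ratio still compares Illumina libraries, as every Hu library is Illumina. The 454 libraries act there only through the scaling, the filter and the estimated spread. Counting 1 tag per position and edgeR's newer quasi-likelihood method were added after the data were examined.

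Each test was tried on simulated counts with known changes, drawn from the real genes' means. In the FMRP against Hu design on 1015 genes, 7.46% of genes changed 2-fold, 55.2% of those changed 4-fold and 93.9% of those changed 8-fold were recovered. In the antibody design on 96 genes these shares were 25%, 75% and 100%, in the age design on 96 genes 12.5%, 87.5% and 100%, and in the protocol design on 334 genes 10.7%, 64.3% and 96.3%. In the antibody and in the age design 24 genes were changed in all, so each share there rests on few genes. Within a design every gene was drawn with the same spread.

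Map1b has no tag in the transcript lists, and Apc has 28 and 14 tags in the FMRP Illumina libraries there against 392 and 262 in the authors' table, so the transcript lists do not carry every gene in full. Map1b was therefore not analysed in the FMRP against Hu comparison. Fmr1-null libraries were not analysed here. A few single genes and 1 genomic bin are not reported here.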

Results

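The data collected were 9 HITS-CLIP libraries of mouse brain polyribosomes at postnatal days 11 to 25. FMRP was precipitated with monoclonal antibodies in 3 libraries (P14, P15 and P25) and with a polyclonal antibody in 2 libraries (P14 and P25), all made with Protocol 1 and read on 454. Protocol 2 and Illumina were used for 2 FMRP libraries with the polyclonal antibody (P11 and P13) and for 2 Hu libraries from the same lysates. The Hu proteins, which bind mRNA and are also found on neuronal polyribosomes, served as the comparison for FMRP. Transcript tags numbered 4397, 6762 and 7713 in the monoclonal libraries, 6533 and 5625 in the polyclonal 454 libraries, 26794 and 44076 in the FMRP Illumina libraries, and 25873 and 49847 in the Hu libraries. At these depths a gene with few tags is measured coarsely, above all on 454.

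The first question was which mRNAs carried most FMRP tags and whether the 7 libraries shared them. Tags per gene were not adjusted for transcript length or mRNA abundance, so their ranking does not measure a preference of FMRP. By the authors' counts, the genes with most FMRP tags were Apc, an antagonist of Wnt signalling that also binds microtubules, with 6323 ± 4153 CPM (tag counts of a gene scaled to a common library total; SD, n = 7), Bsn, which encodes the active-zone scaffold Bassoon, with 6313 ± 1284, and the axonal kinesin gene Kif1a with 5883 ± 1534. Apc owed its rank to the P11 Illumina library, where it reached 15375, and without that library its mean was 4815. The microtubule-associated protein genes Map1a and Map1b followed with 5802 ± 599 and 5726 ± 3872. The adenylyl cyclase gene Adcy1 had 4803 ± 1498, Agap2 had 4736 ± 1801, the latrophilin gene Adgrl1 had 4421 ± 1658, Cyfip2, a partner of FMRP and of the WAVE complex, had 4212 ± 1625, and the calcium pump gene Atp2b2 had 3574 ± 1782. Among genes named in advance, Camk2a had 1673 ± 601, Dlg4 had 1406 ± 358, Shank3 had 883 ± 439, Grm5 had 608 ± 350 and App had 381 ± 231 CPM. Arc (9 tags in the 7 libraries), Gap43 (9), Elavl4 (9) and Fmr1 itself (4) were near the limit of these counts. Per library, 3 counts correspond to at most 682 CPM.

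Tags were found on 10019 genes in at least 1 FMRP library, and 614 genes had a tag in all 7. These 614 genes took 42.0% to 51.5% of the transcript tags of each FMRP library, and 18.3% and 19.2% in the Hu libraries, a contrast partly set by choosing the genes in the FMRP libraries. Across the 500 genes with most tags, Spearman's rho between libraries was 0.706 for the FMRP Illumina pair and 0.878 for the Hu pair, and had a median of 0.530 over the 10 pairs of 454 FMRP libraries. The same measure had a median of 0.393 between 454 and Illumina FMRP libraries, and of -0.0896 between FMRP and Hu on Illumina. Over all genes with a tag in either library, rho was 0.412 for the FMRP Illumina pair, 0.502 for the Hu pair and 0.0163 (median) for the 454 pairs. Genes are not independent replicates, and rho for the FMRP Illumina pair turned to -0.128 once every library was thinned to 4397 tags. At that depth it was -0.0534 for the Hu pair and -0.445 (median) between FMRP and Hu on Illumina.

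The comparison of FMRP with Hu asked which mRNAs on the same polyribosomes were bound more by one protein than by the other. The 10 largest folds towards FMRP were those of genes with 0 Hu tags. Trrap, a scaffold of histone acetyltransferase complexes, had 42 and 49 FMRP tags and none in either Hu library, which is at least 39.6-fold higher in FMRP. The others were Apc2 (at least 34.4-fold higher), the lipid transporter gene Abca2 (at least 31.3-fold), the synaptic Rap regulator gene Sipa1l1 (at least 30.04-fold), the glial glutamate transporter gene Slc1a2 (at least 24.4-fold) and the chromatin remodeller gene Smarca4 (at least 23.1-fold). Sec16a was at least 19.6-fold higher, Akap9 at least 19.2-fold, Rusc2 at least 18.7-fold and the mTOR regulator gene Tsc2 at least 18.3-fold. With genomic tags, which include introns, Sipa1l1, Slc1a2, Smarca4, Akap9 and Rusc2 were below these bounds, at a log2 of 3.23, 3.16, 3.14, 3.21 and 4.08, and still passed. Adjusted p for the 10 genes with transcript tags lay between 0.00211 and 0.00215 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 2 libraries per protein).

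Among the genes with most Hu tags, Calm3 had 238 and 230 Hu tags, with a log2 FMRP over Hu of -3.23 (SE 0.78). Actb, encoding β-actin, was at -2.72 (SE 0.62), the 14-3-3 gene Ywhag at -2.79 (SE 0.66), the sodium pump subunit gene Atp1b1 at -2.79 (SE 0.87), and Qk, an RNA-binding protein gene of myelinating glia, at -2.93 (SE 0.82), and all of these passed the test, Atp1b1 only with the P11 FMRP library included. The SNARE gene Snap25 was at -2.07 (SE 0.91) and did not pass (adjusted p = 0.0714 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed with the lysate as a block, at -2.63 (adjusted p = 0.00116 by the same test), and under further alternatives. Agap2, which was among the 10 genes with most tags for either protein, was at -0.12 (SE 0.52). With 1 tag per position Agap2 was at 1.48 and passed in favour of FMRP, and with all 7 FMRP libraries and a platform term it was at -1.94 and passed in favour of Hu. The latter setting compares the same Illumina tags under another scaling.

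By fold alone the Hu side was led by genes with 0 FMRP tags. Lin7c, which encodes a scaffold of synaptic and epithelial junctions, had 22 and 25 Hu tags (at least 12.0-fold lower in FMRP), and Ptges3 had 22 and 21 (at least 10.97-fold lower). Birc5, Fgf16, Col19a1, Itgb6, Rac2, Acot2, Fgf8 and Sema4b were at least 10.5-fold, 9.19-fold, 9.19-fold, 7.91-fold, 7.66-fold, 7.66-fold, 7.40-fold and 6.89-fold lower. In Birc5, Fgf16, Rac2 and Fgf8 100% of the Hu tags lay in a single window of 100 nt, and in Itgb6, Sema4b and Acot2 96.8%, 96.3% and 90% did. In Col19a1, Ptges3 and Lin7c this share was 72.2%, 65.1% and 23.4%. Genomic Hu tags within the gene bounds numbered 0 in Birc5, Fgf16, Rac2 and Fgf8, 1 in Acot2, and 3 in Itgb6 and in Sema4b. In Col19a1, Ptges3 and Lin7c they numbered 16, 33 and 46. Birc5, Rac2 and Sema4b no longer passed without the P11 Hu library, and Sema4b also not without the P13 FMRP library.

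Of 1015 genes tested, 342 were higher in FMRP and 277 higher in Hu, with 679 at an unadjusted p under 0.05. Among the former, 40 had 0 Hu tags, and among the latter, 13 had 0 FMRP tags. The total of 619 fell to 323 without the P11 Hu library and to 145 of 202 genes with all 7 FMRP libraries and a platform term. The number higher in FMRP was 214 without the P11 Hu library, and the number higher in Hu was 84, 109 and 133 without the P11 FMRP, the P11 Hu and the P13 Hu library. The scaling set the zero point: the median log2 ratio of all genes was -0.17 with TMM, 0.21 with DESeq2's size factors and -0.43 with library totals, and FMRP-higher genes were 55.3%, 61.3% and 46.9% of the calls.

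**Figure D1:**
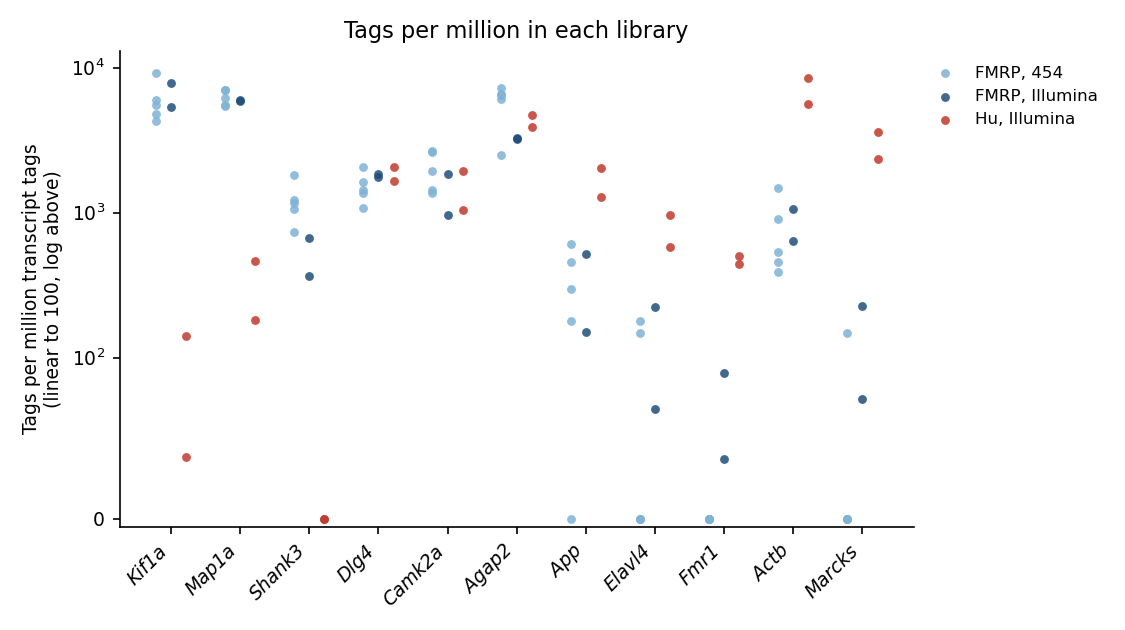
Transcript tags in CPM (linear to 100, logarithmic above) of 11 genes in each library, with 1 point per library: 5 FMRP libraries on 454, 2 FMRP libraries on Illumina and 2 Hu libraries on Illumina. Kif1a lay at 7875 and 5354 in the FMRP Illumina libraries against 38.7 and 140 in the Hu libraries, and Shank3 had 0 tags in both Hu libraries.

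Of the genes named in advance, Shank3, which encodes a postsynaptic scaffold linked to autism, had 18 and 16 FMRP tags and 0 Hu tags, at least 14.8-fold higher in FMRP, but with genomic tags, which include introns, it was at a log2 of 1.29 and no longer passed. Fmr1, the gene of FMRP itself, was lower in FMRP at a log2 of -2.40 (SE 0.68) with 5 FMRP tags against 35 Hu tags. Elavl4, which encodes a neuronal Hu protein, was at -2.22 (SE 0.78) and the amyloid precursor gene App at -1.92 (SE 0.74), and these 3 passed with adjusted p of 0.0145, 0.0328 and 0.0454 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dlg4, encoding the postsynaptic scaffold PSD-95, was at 0.25 (SE 0.55), the kinase gene Camk2a at 0.22 (SE 0.64) and the metabotropic glutamate receptor gene Grm5 at -0.87 (SE 0.66), and none of these passed. With all 7 FMRP libraries and a platform term, Dlg4 and Camk2a turned to -1.58 and -1.77 and passed in favour of Hu. Agap2 and Itpr1 fell as well in that setting, to -1.94 and 0.74. The ratio there still compares Illumina libraries, since every Hu library is Illumina. The tags compared for each gene are those of the main comparison. These falls therefore came with the scaling, which moves the zero point, and the estimated spread, not with other tags of these genes. The passes in favour of Hu there are thus no evidence of a reversal in single genes. Fmr1 no longer passed without the P11 FMRP library or without either Hu library, App without any of these 3, and Elavl4 without either FMRP library or the P11 Hu library. Without the filter on low counts none of these 3 passed, nor did App with edgeR's newer method or Elavl4 with DESeq2 or its size factors. Arc and Gap43 had too few tags for a test.

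The list counts below stand against 342 genes higher in FMRP and 277 higher in Hu among all 1015 tested. Of 16 postsynaptic scaffold and signalling genes tested, 9 were higher in FMRP and 0 higher in Hu, with 9 adjusted over the list alone and a median log2 of 2.27. Shank1 had 173 FMRP tags against 1 Hu tag, a ratio of 226 (95% counting interval 40.0 to 8976), but with genomic tags its log2 was 2.11, still past the threshold. Among 11 presynaptic genes 4 were higher in FMRP and 1 was lower (the same numbers adjusted over the list alone). Unc13a, which encodes a vesicle priming factor, had 83 tags against 1, a ratio of 108 (18.9 to 4333), and Bsn had a log2 of 3.62 (SE 0.62), while the vesicle SNARE gene Vamp2 was at -2.40 (SE 0.65) and did not pass without the P11 FMRP library or without the filter on low counts. The presynaptic median was -0.22 although the mean was 0.82. Of 4 glutamate receptor genes only Grik5 was called, with 66 tags against 3, a ratio of 28.7 (9.41 to 143), and the list had 1 call adjusted over the list alone. Of 11 voltage-gated channel genes 6 were higher in FMRP, also adjusted over the list alone, among them Kcnq3 (at least 12.2-fold, or a log2 of 2.80 with genomic tags) and the pacemaker channel gene Hcn2 (at least 10.4-fold), with a list median of 1.96.

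Regulatory and structural lists showed larger medians. Of 20 chromatin regulators 16 were higher in FMRP, and 16 adjusted over the list alone, with a median log2 of 3.86. The acetyltransferase gene Crebbp had 105 tags against 1, a ratio of 137 (95% counting interval 24.1 to 5468; a log2 of only 1.68 with genomic tags, still past the threshold), and the remodeller gene Chd3 a log2 of 5.24 (SE 0.77). Of 17 small GTPase regulators 12 were higher in FMRP (13 adjusted over the list alone; median 3.41), including Herc1 at 4.42 (SE 0.72) and Dock9 at 4.17 (SE 0.73). Of 17 cytoskeleton and motor genes 10 were higher in FMRP, and 10 adjusted over the list alone, with a median of 4.12, or 3.80 with the gene at 0 Hu tags set to its bound. The dynactin gene Dctn1 was at least 13.9-fold higher and Dst at 4.44 (SE 0.68). Of 7 PI3K-mTOR genes 5 were higher (6 adjusted over the list alone; median 3.42), with Mtor at 51 tags against 1, a ratio of 66.6 (11.4 to 2682).

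Of 17 adhesion and guidance receptor genes 13 were higher in FMRP and 1 lower (14 and 1 adjusted over the list alone; median 2.63). The examples are Fat2, with 26 tags against 1 and a ratio of 33.96 (95% counting interval 5.58 to 1392), and the cell adhesion gene Ncam1 at -2.73 (SE 0.70), which did not pass without the P11 Hu library. Of 16 autism-risk genes 6 were higher in FMRP and 0 lower (5 adjusted over the list alone; median 1.38). The share higher in FMRP was close to that of all tested genes (342 of 1015). RNA-binding protein genes went the other way, with 1 of 8 higher and 6 lower in FMRP (1 and 7 adjusted over the list alone; median -2.27). Elavl1 was at -3.51 (SE 0.95) and did not pass without the P11 FMRP library, while the translational repressor gene Pum2 was higher in FMRP at 3.53 (SE 0.76), or 1.06 and not passing with genomic tags. All 4 tested genes of the known Hu-bound list were lower in FMRP (4 adjusted over the list alone; median -3.11), with Marcks at -3.86 (SE 0.74). The Hu-bound and RNA-binding lists share Elavl1 and Elavl4.

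**Figure D2:**
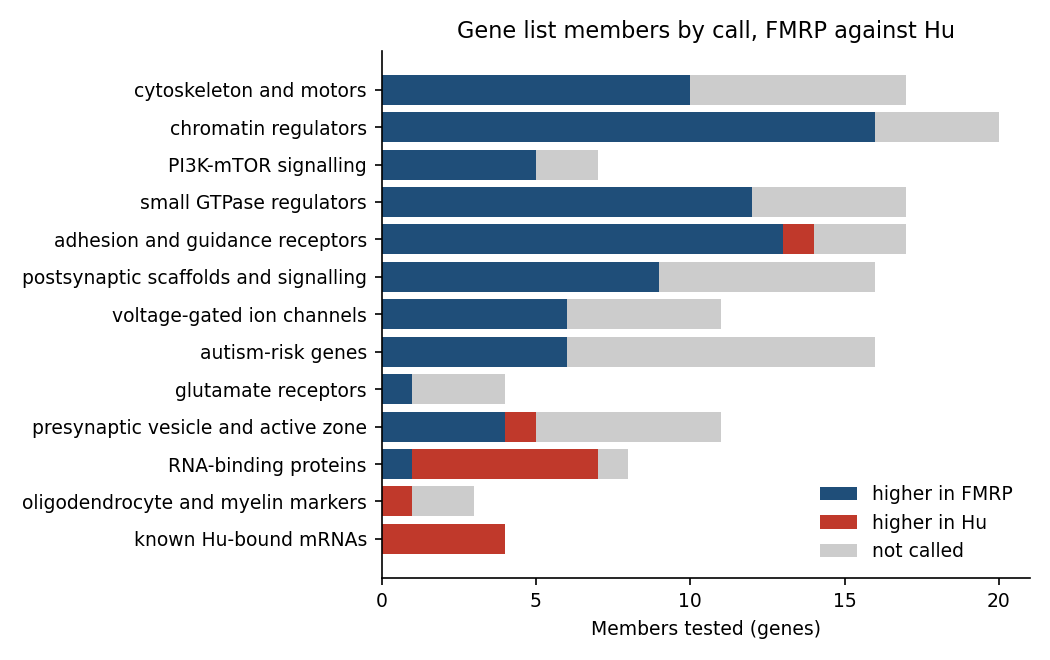
Number of tested genes (horizontal axis) of each of the 13 gene lists with at least 3 tested members, divided into genes higher in FMRP, higher in Hu and not called. Chromatin regulators had 16 of 20 members higher in FMRP, and all 4 tested Hu-bound mRNAs were higher in Hu.

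Glial and other marker lists were thinly covered. Of 3 tested oligodendrocyte and myelin genes 1 was lower in FMRP (3 adjusted over the list alone; median -2.45), with Ugt8a at -3.69 (SE 0.89). Of 2 astrocyte genes tested, Slc1a2 was higher in FMRP, and of 2 cerebellar genes the calcium channel gene Itpr1 was, at 2.85 (SE 0.89), though it did not pass without the P11 Hu library, or with the platform term, where it fell to 0.74. Both tested genes of oxidative phosphorylation, the ATP synthase genes Atp5b (71 tags against 3, a ratio of 30.9 with a 95% counting interval of 10.2 to 153) and Atp5a1 (log2 of 2.49, SE 0.67), were higher in FMRP, and Atp5a1 did not pass without either Hu library or without the filter on low counts. No ribosomal protein, activity-induced, microglial or endothelial gene had enough tags for a test. Their FMRP and Hu tags on Illumina summed to 32 and 21, 32 and 62, 5 and 1, and 2 and 1.

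As sets, 8 of the 13 lists passed camera with Benjamini-Hochberg adjustment at a preset correlation. Adjusted p was 9.28e-05 for chromatin regulators, 0.00156 for small GTPase regulators and for the cytoskeleton, 0.00261 for adhesion receptors, and 0.0301 for postsynaptic, PI3K-mTOR, voltage-gated and Hu-bound genes. For RNA-binding proteins it was 0.0673, for autism-risk genes 0.0752, for myelin genes 0.136, and 0.747 for both glutamate receptors and presynaptic genes. None of the 8 passed once the correlation was estimated: adjusted p = 0.223 with an estimated correlation for chromatin, small GTPase, cytoskeleton and adhesion genes, 0.320 for PI3K-mTOR, 0.346 for Hu-bound, 0.385 for voltage-gated and 0.405 for postsynaptic genes. With the lysate as a block, RNA-binding and myelin genes passed as well (adjusted p = 0.0382 and 0.0460 by camera), and these too did not with an estimated correlation (adjusted p = 0.560 for both). Lists also gained: RNA-binding genes passed with genomic tags (adjusted p = 0.0110 by camera), autism-risk genes without the P11 or the P13 FMRP library (0.00369 and 0.00735) and myelin genes without the P11 Hu library (0.0238). With genomic tags the postsynaptic, voltage-gated and adhesion lists did not pass (adjusted p = 0.202, 0.116 and 0.0601), nor did the voltage-gated list without the P13 FMRP library (0.149).

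Where on the mRNA the tags lay differed between the proteins. In the authors' counts, 81.1% ± 5.55 (SD, n = 7) of FMRP tags on mRNAs lay in coding sequence, against 56.0% ± 1.53 if the same tags were spread evenly along their transcripts, and the share was above that level in 7 of 7 libraries. It ranged from 69.7% (95% Wilson interval 69.3 to 70.2) in the P13 Illumina library to 86.7% (85.6 to 87.7) in the P14 monoclonal library. Group means were 85.0% ± 1.57 (SD, n = 3) for the monoclonal mix, 80.7% ± 1.95 (SD, n = 2) for the polyclonal antibody on 454 and 75.7% ± 8.42 (SD, n = 2) on Illumina. For 454 against Illumina the exact permutation p was 0.190, and with 5 against 2 libraries it cannot fall below 0.0952. Along the transcript, the part beyond 0.75 of its length held 8.38% ± 1.38 of FMRP tags (SD, n = 7) and 29.4% ± 0.137 of Hu tags (SD, n = 2). The exact permutation p was 0.0556, the smallest that 7 against 2 libraries can give. Among Illumina libraries alone the FMRP share was 9.86% ± 1.48 (SD, n = 2), and 2 against 2 libraries cannot reach an exact permutation p below 0.333, the value obtained. Within single genes with at least 10 tags for each protein, Hu tags lay further 3′ in 617 of 649 genes, by a median of 0.225 of the transcript length.

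**Figure D3:**
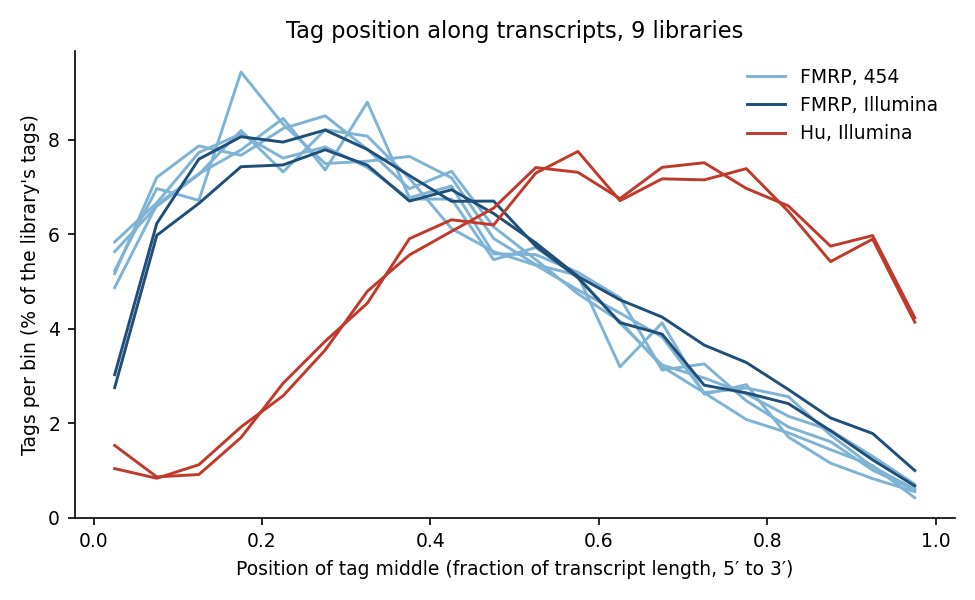
Share of each library's tags (vertical axis, % per bin) by position of the tag middle along the transcript (horizontal axis, fraction of length from 5′ to 3′), with 1 line per library for 7 FMRP and 2 Hu libraries. Median positions were 0.333 to 0.383 in the FMRP libraries and 0.603 and 0.609 in the Hu libraries.

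Tags of the 2 proteins also differed in how they piled up. At 4397 tags per library, 0% of FMRP tags in each of the 7 libraries had at least 10 overlapping tags, while 2.16% and 1.02% of the tags in the P11 and P13 Hu libraries did (mean 1.59% ± 0.801, n = 2; exact permutation p = 0.0556). A share of 0 of 4397 tags still allows up to 0.0682%. With genomic tags the order turned, at 4.39% ± 1.25 for FMRP (SD, n = 7) and 1.12% ± 0.0328 for Hu (SD, n = 2). Without a block of 3 kb on chromosome 17 outside gene bounds, it was 2.09% ± 0.858 for FMRP (SD, n = 7) and 0.979% ± 0.0499 for Hu (SD, n = 2). Other bins outside gene bounds with many FMRP tags were left in, so the genomic values do not show more clustering of FMRP on genes.

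FMRP over Hu rose with the length of the coding sequence. Across 944 of the tested genes (93.0% have a length), Spearman's rho of the log2 ratio was 0.763 with coding length and 0.405 with transcript length. Both had a permutation p of 1e-05, the smallest that the resampling can give and unaltered by Benjamini-Hochberg adjustment over these 2 relations. Genes are not independent replicates. Genes higher in FMRP had a median coding length of 4740 nt, those higher in Hu 1041 nt, and those not called 2156 nt. Of the 315 genes with the longest transcripts, 157 were higher in FMRP and 38 higher in Hu, and of the 315 with the shortest, 50 and 157.

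**Figure D4:**
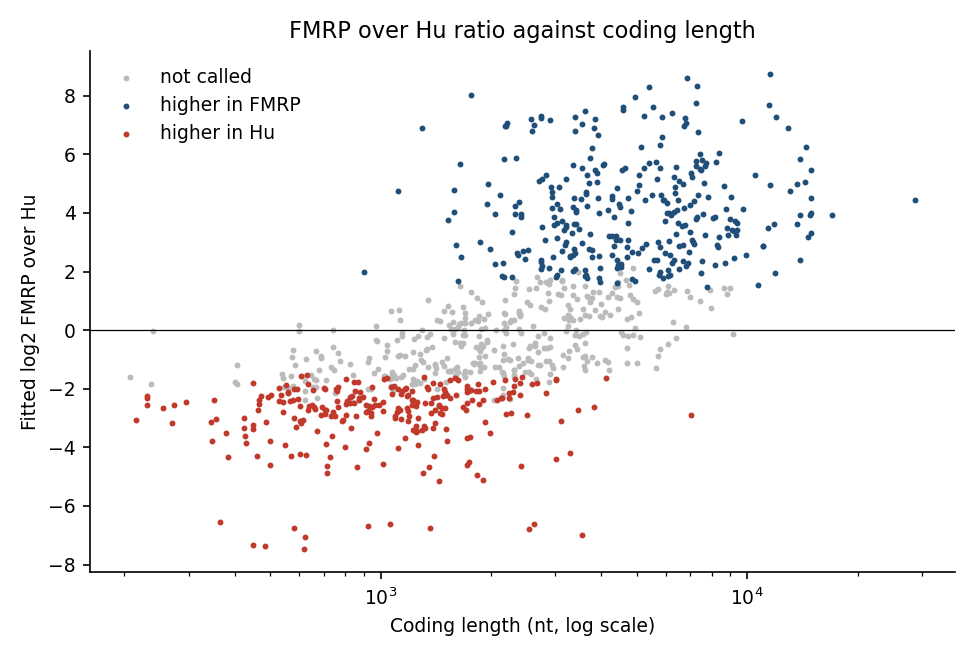
Fitted log2 ratio of FMRP over Hu (vertical axis) against coding length in nt (horizontal axis, logarithmic) for 944 tested genes, coloured by whether they were higher in FMRP, higher in Hu or not called. Spearman's rho was 0.763.

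The antibody comparison asked whether the monoclonal mix and the polyclonal antibody brought down the same mRNAs. Among 96 genes tested in the 454 libraries, 0 passed by edgeR's quasi-likelihood test or by DESeq2, with 4 and 0 at an unadjusted p under 0.05. The smallest p were those of Adgrb1, an adhesion receptor gene, with a log2 of polyclonal over monoclonal of 1.23 (SE 0.54), and Kif1b with 0.68 (SE 0.34). In the other direction they were Celsr2 with -1.04 (SE 0.50), Grik5 with -1.08 (SE 0.54) and Dlgap1 with -1.21 (SE 0.63). Tags for Adgrb1 were 19 and 12 in the polyclonal libraries and 6, 7 and 9 in the monoclonal ones. None of the 7 lists tested passed camera, with a smallest adjusted p of 0.277. Counts of this size could not show a 2-fold difference reliably, since 25% of simulated ones, which were few, were recovered.

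For age, 1 of 96 genes passed. Arhgap32, encoding a neuronal GTPase-activating protein, had 26 and 17 tags at P25 against 8, 6 and 8 at P14 and P15, a log2 of 1.49 (SE 0.42), with adjusted p = 0.0484 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was higher in both P25 libraries than in any younger one. The smallest p among genes lower at P25 were those of Nav3 at -1.14 (SE 0.62), Grik5 at -0.91 (SE 0.51) and Auts2 at -1.96 (SE 1.15), and none of these passed. No list passed camera, with a smallest adjusted p of 0.503. The Arhgap32 call was lost in each alternative tried except edgeR's newer quasi-likelihood method, leaving out any 1 of the 5 libraries included, with adjusted p from 0.0718 to 0.986 where it was lost.

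For protocol, platform and age, which change together between the polyclonal 454 and Illumina libraries, 28 of 334 genes passed, 14 in each direction, with 84 at an unadjusted p under 0.05. Higher on Illumina were Arhgap5, with 63 tags against 0 (at least 4.45-fold), the clathrin heavy chain gene Cltc at a log2 of 2.74 (SE 0.65), the dynein heavy chain gene Dync1h1 at 2.57 (SE 0.56), the spectrin gene Sptbn1 at 2.45 (SE 0.58), Nckap1 at 2.47 (SE 0.70), Usp9x at 2.36 (SE 0.67) and Dmxl2 at 2.34 (SE 0.63). Ids and Rapgef2 had 1 tag on 454 against 71 and 64, ratios of 15.05 (95% counting interval 2.62 to 603) and 13.6 (2.35 to 544). Map1b was higher at 1.75 (SE 0.48). Lower on Illumina were Zfhx2 at -3.19 (SE 0.42), the tubulin gene Tubb4a at -2.74 (SE 0.25), the neurogranin gene Nrgn at -2.48 (SE 0.47) and Adgrb1 at -2.05 (SE 0.54), besides Mtcl1, Trpc4ap, Phyhip, Map3k10 and Ppp6r2 between -2.81 and -2.28. Dlg4 (0.63, SE 0.52), Camk2a (-0.56, SE 0.51) and Shank3 (-1.22, SE 0.62) did not pass.

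The cytoskeleton and motor list was higher on Illumina, with 3 of 17 members called (9 adjusted over the list alone) and a median log2 of 1.25, at an adjusted p of 0.00641 by camera, and adjusted p = 0.762 with an estimated correlation. Leaving out either 454 library left 1 or 2 genes in all, and DESeq2 called 11. Library totals without TMM gave 4 genes higher and 16 lower on Illumina. Without the filter on low counts 27 were higher and 0 lower, so that each gene lower on Illumina lost its call. Tags sharing a position were 0% of transcript tags in each 454 library, where merging reads by position would leave none. In the P11 and P13 FMRP Illumina libraries they were 13.7% and 5.94%. With 1 tag per position 18 genes passed. Of the 14 main calls in each direction, 12 and 9 were tested there, and 6 and 7 kept their call.

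The authors' deposited table marks 839 genes at an FDR under 0.01, of which 632 have a tag in all 7 FMRP libraries. Of the 1008 tested genes found in the authors' deposited table, 481 are so marked. They made up 286 of the 342 genes higher in FMRP than in Hu (83.6%; 163 by independence; Fisher's exact test, p = 1.88e-63) and 22 of the 273 genes higher in Hu (8.06%). The authors' deposited table and the present comparison use the same FMRP Illumina libraries, so the overlap is not between independent data. In the authors' deposited table Bsn and Kif1a have a chi-square statistic of 133 and 126. The 5 gene collections marked there were tested against the calls in each direction with Fisher's exact test. Only the postsynaptic proteome passed, as less frequent among Hu-higher genes (51 members, 18.4% against 27.8% of other genes; Benjamini-Hochberg adjusted p = 0.0204 over 10 tests). Among FMRP-higher genes its share was 26.6% against 24.5% of other genes and did not pass (adjusted p = 0.702 by the same test).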

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

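The genomic positions below were chosen only after the data were seen, as those with most tags outside the gene bounds of the authors' table. Coordinates are mm9. No test was run on these values, and no explanation was weighed for them.

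Mitochondrial RNA was more frequent with FMRP than with Hu in the same lysates, in tags that the comparisons of genes did not use. It made up 0.298% (95% Wilson interval 0.251 to 0.354) of the genomic tags of the P11 FMRP library and 1.27% (1.19 to 1.36) of the P13 FMRP library, against 0.0338% (0.0219 to 0.0523) and 0.197% (0.172 to 0.227) in the Hu libraries. In the 454 FMRP libraries the share was 0.0134% to 0.290%.

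A block of 3 bins of 1 kb on chromosome 17, starting at 39983001 and lying between the genes Olfr136 and Pgk2 of the authors' table, held 3.48% of the genomic tags of the P11 FMRP library and 3.43% of the P13 FMRP library. The Hu libraries had 0.315% and 0.247% there, and the 454 FMRP libraries 2.21% to 3.01%. In the RefSeq annotation of GRCm38 Rn18s-rs5, a pseudogene of 18S ribosomal RNA by its name, lies between the same 2 genes.

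Hu tags outside gene bounds piled up in bins of 1 kb in which the P13 Hu library had more tags than the P13 FMRP library. The bin on chromosome 6 from 47731001, between Ezh2 and Pdia4, held 462 tags against 24, and in the RefSeq annotation of GRCm38 the Y RNA genes Rny1 and Rny3 lie between these neighbours. The bin on chromosome 8 from 15519001, between BB014433 and Csmd1, held 288 against 37. Between Mbp and Zfp236 on chromosome 18 from 82753001 the P13 Hu library held 162 tags against 17, and between Mul1 and Ubxn10 on chromosome 4 from 138013001 it held 182 against 27.

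For the 11 tested presynaptic genes the median log2 of FMRP over Hu was above 0 in the P11 lysate, at 0.0019, and below 0 in the P13 lysate, at -0.07, a difference of -0.0745. With 1 pair of libraries per age this difference was not tested. It was flagged for its change of sign only, and other lists moved further without one, among them myelin genes by 1.56, Hu-bound mRNAs by 1.26, glutamate receptors by 0.89 and autism-risk genes by -0.57, also untested.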

How the results depend on the processing

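The alternatives with 1 tag per position, clustering without the densest block, P14 and P25 libraries without an age term for antibody, edgeR's newer quasi-likelihood method, list tests on genomic tags or with DESeq2's size factors, the block combined with an estimated correlation, and all list alternatives outside FMRP against Hu were chosen after the data were seen. For FMRP against Hu, 0 of the 619 calls were called in the other direction in any alternative, though 4 changed sign uncalled with genomic tags and 4 with the platform term. Of the 342 main calls higher in FMRP and 277 higher in Hu, 285 and 158 were tested with genomic tags, where 254 and 144 kept their call. Without the filter on low counts 226 and 96 kept it. The total lay between 528 and 715 under the other scalings, tests and tag choices, though not always with the same genes. It was 323 to 532 without single libraries (higher in FMRP 214 to 422, higher in Hu 84 to 283), where a lone library is assumed to vary like the other group, and 145 (82 and 63) with all FMRP libraries and a platform term, which tested 202 genes. Without the filter 155 genes were higher in Hu, with 10341 genes in the adjustment. With the lysate as a replicate block 603 genes passed, 330 higher in FMRP and 273 higher in Hu, of which 322 and 236 were main calls. Of the genes named in these texts the block changed the call of Snap25 only, and of lists those of RNA-binding proteins and myelin only. It left the antibody comparison at 0 genes.

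When the genes picked for FMRP against Hu were compared with each alternative, 683 kept direction and side of the threshold, 32 lost the call, 18 gained one and 3 reversed: Dlg4 to -1.58 and Camk2a to -1.77 with the platform term, and Agap2 to 1.48 with 1 tag per position, of which none was called before. With the platform term Agap2 was at -1.94 and passed as well, and Itpr1 fell to 0.74 and lost its call. With genomic tags the log2 of Crebbp fell to 1.68 and that of Shank1 to 2.11, and both kept their call. The cause was not tested for any of these. With the platform term the ratio still compares Illumina libraries, and the 454 libraries act only through the scaling, the filter and the estimated spread. The shifts with the platform term therefore came with a moved zero point and the estimated spread, not with other tags of these genes. Leaving out the P11 Hu library cost 9 genes their call, more than any other alternative did.

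The Hu share beyond 0.75 of the transcript was 28.5% with the tag start in place of its middle. With at least 5 overlapping tags, clustering was 0.319% for FMRP and 4.70% for Hu. It was 4.39% for FMRP with genomic tags, 2.09% with these but without the block on chromosome 17, and 0.587% for Hu with 1 tag per position. For the FMRP Illumina pair, Spearman's rho was 0.483 for genes with a mean of at least 10 tags and -0.128 after thinning to 4397 tags, where the Hu pair was at -0.0534 and pairs of FMRP with Hu at -0.445. The cause of these changes was not tested.

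For age the single call became 0 with DESeq2's size factors, library totals only, no filter, the DESeq2 test, genomic tags, the transcript tag files, no antibody term, P14 and P25 libraries only, and without any single library (0 to 0). For protocol DESeq2 called 11 genes, 1 tag per position gave 18, and leaving out single libraries gave 1 to 20, and the cause was not tested. Without the filter 27 were higher and 0 lower on Illumina, and the 14 lower ones all lost their call. With an estimated correlation 0 lists passed for FMRP against Hu, 0 with the replicate block and an estimated correlation, and 0 for antibody, age and protocol, and the cause was not tested. Restricting the length relation to a mean of at least 50 CPM removed no gene and tests nothing. For tag regions, all genomic tags and priority of 3′ UTR over coding sequence were not run, as both need an annotation of mm9, which was not used here.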

Other observations

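Tests chosen only after the result was seen were those of reads matching several genome positions and of a single Hu site, and the transcript-length test for the chromatin and cytoskeleton lists alone. The coding-length test was set once the correlation with coding length was known, the check of background without Hu-enriched genes was added after its first value, and the test of carry-over on the rise alone, with its 512 genes, after the first test of carry-over. Genes in the next paragraph were chosen after their values were seen.

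In the PI3K-mTOR list the translation initiation factor gene Eif4g1 and the autophagy kinase genes Ulk1 and Ulk2 were higher in FMRP, at a log2 of 4.05 (SE 0.90), 3.42 (SE 0.70) and 2.05 (SE 0.68). Among RNA-binding protein genes Celf2 at -1.89 (SE 0.65) and Msi2 at -2.32 (SE 0.91) were higher in Hu. Among glutamate receptor genes Grin2b was at 1.51 (SE 0.70) and Gria2 at -1.05 (SE 0.68), and neither passed. The astrocyte gene Glul was at 0.70 (SE 0.85) and the cerebellar gene Zic1 at -1.25 (SE 0.72), and neither passed.

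The P13 FMRP library held more tags on Hu-enriched mRNAs than the P11 FMRP library: on 283 genes called higher in Hu without the P13 FMRP library lay 6.13% of its tags (95% Wilson interval 5.91 to 6.36), against 1.65% at P11, a share that this choice of genes lowers, 2.30% to 3.45% in the 454 FMRP libraries and 29.6% and 29.2% in the Hu libraries. On 512 genes picked without either library, by at least 20 Hu tags and a 4-fold excess over the 454 FMRP libraries, it was 9.25% (8.98 to 9.52) against 5.01% (4.76 to 5.28). Of the P13 FMRP tags on the 283 genes 13.4% (12.2 to 14.8) lay in each gene's densest P11 Hu window, where carry-over from the P13 Hu library had been set to need at least 21.6%. That test ignored tags present without carry-over. For the rise alone on the 283 genes the share was 17.3% (14.3 to 20.4), below the bound by more than its interval (difference -4.35, interval -6.94 to -1.65). For the rise on the 512 genes it was 17.8% (13.4 to 22.2, genes resampled) against 20.9% (difference -3.09, interval -7.42 to 0.959). The 283 genes go against carry-over, but their choice used the P11 FMRP library, and the 512 genes do not decide. Carry-over can therefore not be told apart from other causes. A general mRNA background is a candidate explanation as well: the rise from P11 to P13 correlated with exon array intensity across 968 genes at rho = 0.257 (permutation p = 1e-05, the smallest possible), and at 0.245 without the Hu-enriched genes. Background alone leaves unaccounted that the rise fell on Hu windows more than the P11 FMRP tags did (7.37% on the 512 genes), and the difference in age was not tested.

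In 26 of the 277 genes higher in Hu, at least 90% of Hu tags fell in 1 window of 100 nt, and in 0 of the 342 genes higher in FMRP did FMRP tags do so. Of the 1002 Hu tags of these 26 genes, 23 (2.30%) were placed as the same read outside the gene on the genome. Inside the gene lay 85, and 894 (89.2%) were not found. In the other genes higher in Hu 30.1% were placed in the gene, 0.979% elsewhere and 69.0% were not found. With so few reads followed, the low share elsewhere cannot decide whether reads from another locus are the whole cause. Among reads that were found, 23 lay elsewhere against 85 inside, and in the other genes higher in Hu 175 against 5375. The 23 of these genes with bounds had a median of 0.0811 genomic tags per transcript tag, against 0.898 in the other genes higher in Hu, as reads that match several genome positions and are unique only among transcripts would give, so this may explain part of these calls, Birc5, Fgf16, Rac2 and Fgf8 included. A single Hu site cannot be told apart from it, since 8.48% of these tags were placed inside their gene against the 30.1% above, and reads across exon junctions would also lack a genome position. Apart from such a site no biological explanation was tested, as the groups of the design give none.

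The 7 lists higher in FMRP had median coding lengths of 3010 to 7334 nt, against 2156 nt in genes not called, and median transcript lengths of 6308 to 11905 nt against 6341 nt. Against 10000 random lists matched on transcript length, 2 of the 7 lists, chromatin regulators and cytoskeleton, had a median above the central 95%, with a lower percentile of 99.57. These 2 were singled out by this same outcome, and 2 of 7 was fewer than had been set beforehand to count against transcript length. Transcript length alone can therefore not be excluded for any of the 7. Against random lists matched on coding length 0 of 7 had a median above the central 95%, with percentiles from 12.67 to 91.18. Coding length alone may thus account for the medians of the members with a length. Members without one were left out, so the postsynaptic median compared was 0.52, from 13 of 16 members, in place of 2.27. Whether long coding sequences offer more room for FMRP, or FMRP prefers these mRNAs for another shared property, was not tested and no group of the design bears on it.

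Between Illumina libraries, 6354 pairs of tags had the same position, of which 0 shared a barcode, where 46.6 would share one by barcode frequency.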
